A study of Mus musculus with 6 samples.

How the data were processed

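RNA was measured in spermatogonial stem cells sorted as THY1-positive and c-KIT-negative from C57BL/6J testes at postnatal day 4, in 3 wild type and 3 Bud31-vKO libraries made by Smart-Seq2, per the labels' protocols. The deposited values are whole-number read counts per Ensembl gene, with no scaling, as their unequal totals show. Reads were written with bcl2fastq and the genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation release and whether strand was used are not given in the sources used here. The columns of the table carry the letters C and T with numbers 1 to 3. They were assigned to wild type and Bud31-vKO libraries 1 to 3 by convention before any gene was looked at by group, since the labels do not spell the letters out. The RNA immunoprecipitation profiles of the series were not used here.

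The table held 51912 genes, of which 24531 had no reads in any library, and 51633 of the identifiers (99.5%) received a symbol from GENCODE M21 on GRCm38, the assembly also called mm10. Library totals were 13577015, 18744466 and 17131113 reads for wild type and 13240704, 14507038 and 13722761 reads for Bud31-vKO. A level of 3 reads, taken as the floor, equals 0.160 to 0.227 CPM depending on the library. This floor covers counting error only, not the spread between samples. Where a group had no reads, folds were bounded against that floor. Gene coordinates, the largest number of exons in any transcript of a gene, and the length and GC content of its longest transcript came from the same annotation. Exons that overlap those of another gene were noted, since reads there cannot be told apart without strand.

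Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 15240, and libraries were scaled by TMM. The 2 genotypes were compared with edgeR's quasi-likelihood F test without covariates, and p-values were adjusted by the Benjamini-Hochberg method at 5%. CPM are scaled with the TMM factors, and error values are SD over the 3 libraries of a group unless called standard error. An exact permutation test of 3 libraries against 3 cannot go below 0.1, so none was used for single genes. Analyses ran in R 4.3.3, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

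The lists of genes were written before the data were seen. They cover stem cell, progenitor, pan-germ-cell, piRNA and meiosis genes, spliceosome and SR protein genes, p53 targets, apoptosis, G1/S, G2/M, stress response, immediate early, retinoic acid, ribosomal and mitochondrial genes, and markers of Sertoli, Leydig, peritubular myoid, stromal, endothelial, macrophage, T and erythroid cells. Each list with at least 4 tested members, 24 of 26, was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with the correlation estimated from the data. Members were also adjusted over their list alone. The relation of fold change to exon number was taken as Spearman's rank correlation over 13172 protein-coding genes, with a rank regression on transcript length, GC content and mean expression beside it.

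The rule for naming genes, also written beforehand, took Bud31, Thy1, Kit and Cdk2, then the 10 largest rises and falls among genes past the threshold with a mean log2 CPM of at least 4, an ordinary symbol and no overlap between groups, then the 3 members of each list with the smallest adjusted p, ties going to the larger fold change. It named 78 genes, none by its middle part, and some of them are not reported here. As nearly all adjusted p tied, the list members named are mostly those with large fold changes, many at low counts. Genes added after their values were seen are marked as such in the text.

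Alternatives were RLE, upper-quartile and library-size scaling, no filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a block for the library number, removal of mitochondrial, haemoglobin and ribosomal RNA genes, each library left out in turn, fry in place of camera, and a 2-fold threshold. Added after the first results were robust dispersion, a mean of at least 50 CPM, and the 4 libraries with the most genes detected. A smooth trend on length, GC content and mean expression was fitted with mgcv 1.9.3. Bootstrap standard errors used 10000 draws of genes and do not measure the spread between libraries.

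The steps were tested on simulated data. With the dispersion of these libraries edgeR recovered 0 of 50 genes changed 2-fold, 2 of 50 changed 4-fold, 8 of 50 changed 8-fold and 8 of 50 changed 16-fold, with 0 false calls. With a dispersion of 0.05 it recovered 29, 49, 50 and 49 of 50, with 10 false calls. Of 20 lists of 25 genes shifted by 1 on the log2 scale, camera recovered 12, and it called 0 of 80 unshifted lists. The simulated genes were independent of one another. The estimated correlation was 0.656 in the ribosomal list and 0.498 in the G2/M list. The simulation thus does not show how often camera calls such lists in error at the preset correlation.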

Results

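Gene expression was measured by Smart-Seq2 RNA sequencing, a full-length cDNA amplification for small amounts of RNA, in spermatogonial stem cells from the testes of C57BL/6J mice at postnatal day 4. The cells were sorted by flow cytometry as THY1-positive and c-KIT-negative, a surface pattern used to enrich the stem cells that maintain the male germ line. The 6 libraries fell into 3 wild type and 3 Bud31-vKO libraries, the latter from mice in which Bud31 was deleted with Cre recombinase and loxP sites. BUD31 is a protein of the spliceosome, the machinery that removes introns from pre-mRNA, and the comparison asked which genes and gene groups differ in these cells when Bud31 is deleted. The count table covered 51912 genes, and its totals were 13577015, 18744466 and 17131113 reads in wild type libraries 1 to 3 and 13240704, 14507038 and 13722761 reads in Bud31-vKO libraries 1 to 3. The table names its columns with the letters C and T in place of the genotypes. C was read as control, hence wild type, and T as the targeted genotype, by the usual convention and before any gene was looked at, and the labels do not spell the letters out. Nothing in the labels says that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical. The profiles of RNA immunoprecipitation that the series also mentions were not analysed here.

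The libraries differed strongly from one another within each genotype. Reads were found for 22300, 18171 and 13762 genes in wild type libraries 1 to 3, and for 20286, 12464 and 18997 genes in Bud31-vKO libraries 1 to 3. Wild type library 3 and Bud31-vKO library 2 thus stood apart with few genes detected, at totals of 17131113 and 14507038 reads. Pearson's r of log2 CPM (reads scaled to library size) across genes lay between 0.617 and 0.820 for the 6 pairs of libraries of the same genotype and between 0.591 and 0.803 for the 9 pairs of different genotype. The biological coefficient of variation over all tested genes, a measure of the spread between libraries beyond counting error, was 119%.

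Bud31, the deleted gene, was lower in each Bud31-vKO library than in any wild type library. Its level was 131 ± 31.1 CPM (SD, n = 3) in wild type and 65.1 ± 16.7 CPM (SD, n = 3) in Bud31-vKO. The separate values were 138, 96.8 and 158 CPM in wild type and 47.2, 67.6 and 80.4 CPM in Bud31-vKO, from 646 reads or more per library. The log2 fold change was -1.01 with a standard error of 0.39, a 2.01-fold lower level. By edgeR's quasi-likelihood test the unadjusted p was 0.0345 and the adjusted p 0.9997. Bud31 (ENSMUSG00000038722) lies on chromosome 5 from 145140362 to 145148078 on the plus strand of GRCm38, and its exons overlap Ptcd1 on the opposite strand. Reads of the remaining exons and of cells outside the germ line still count toward the gene, and the labels do not say which exons were deleted. The direction goes with the reading of the column letters.

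Among the genes named by a rule written beforehand, Cdk2 had the smallest p. Cdk2, a kinase that drives cells from G1 into DNA replication, measured 218 ± 53.4 CPM (SD, n = 3) in wild type and 45.6 ± 11.7 CPM (SD, n = 3) in Bud31-vKO, a 4.78-fold lower level with no overlap between the groups. Mael, a component of the piRNA pathway that silences transposons in germ cells, measured 493 ± 165 CPM against 156 ± 42.5 CPM, and Etv5, a transcription factor of stem cell self-renewal, 242 ± 92.9 CPM against 80.2 ± 54.5 CPM (SD, n = 3 each). Clk1, a kinase that phosphorylates splicing factors, was the rule's gene with the smallest p among those higher in Bud31-vKO, at 421 ± 101 CPM against 194 ± 45.2 CPM (SD, n = 3 each). By edgeR none of these genes passed the test over all 15240 genes.

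**Figure D1:**
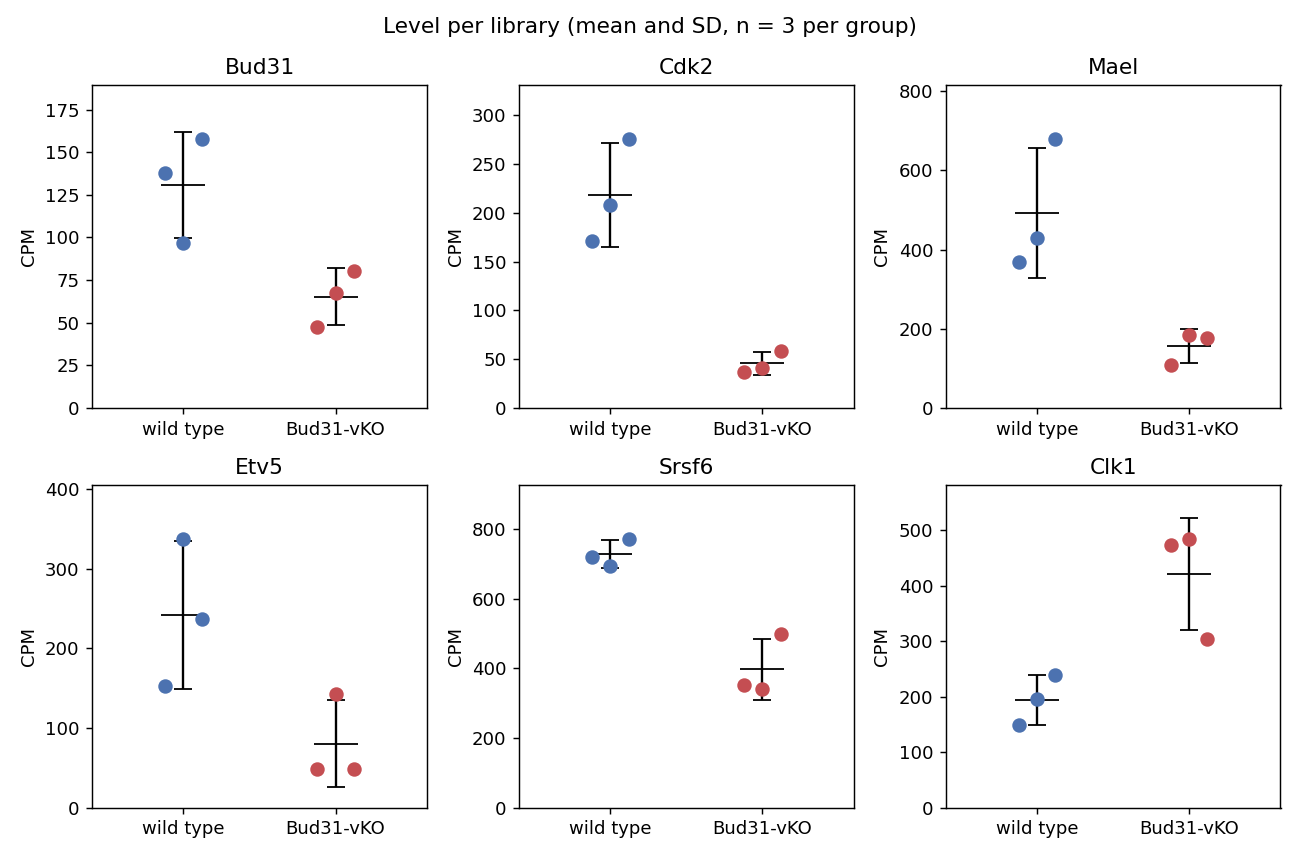
Level in CPM (vertical axis, starting at 0) of 6 genes in each library, wild type in blue and Bud31-vKO in red, with the mean as a horizontal line and the SD as a bar (n = 3 per group). The 3 Bud31-vKO libraries lie below the 3 wild type libraries for Bud31, Cdk2, Mael, Etv5 and Srsf6 and above them for Clk1, and no gene of the 6 passed 5% over all genes tested with edgeR.

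By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 genes were higher and 0 lower in Bud31-vKO, and the smallest adjusted p was 0.9997. At an unadjusted p under 0.05 there were 443 genes, 165 higher and 278 lower, where 762 would be found by chance alone. Groups did not overlap for 11.2% of the genes, against 10% by chance for 3 libraries against 3. DESeq2 on the same counts called 17 genes higher and 30 lower, and limma-voom 0 and 0. Cdk2 was among the DESeq2 calls with an adjusted p of 0.000276, as was Mael with 0.0453. At an unadjusted p under 0.05 DESeq2 had 753 genes, near the 762 by chance. Simulated genes, and the splits of the libraries given below, were tested with edgeR and not DESeq2. How often DESeq2 calls genes in error in these libraries was thus not checked. No other setting called either gene over all genes. Cdk2 was placed in the rule by name, from background knowledge and not from the labels, so its choice is not independent evidence. Its log2 fold change was -2.26 with a standard error of 0.38 and an unadjusted p of 0.000368. It lies on chromosome 10 from 128697939 to 128705031 on the minus strand, and its exons overlap Pmel on the opposite strand, whose reads could not be told apart if strand was not used in the counting. Pmel itself was counted at 19.7, 16.8 and 14.2 CPM in wild type libraries 1 to 3 and at 0.37, 16.3 and 0.22 CPM in Bud31-vKO libraries 1 to 3.

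Genes singled out after their values were seen include the 7 that edgeR called when no filter on low counts was applied. H2-K1, a class I histocompatibility gene, was higher in Bud31-vKO with a log2 fold change of 2.44 and a standard error of 0.45, from 92.0 ± 27.0 to 501 ± 245 CPM (SD, n = 3 each). The other higher genes were H2-Q6 and Car2, which encodes a carbonic anhydrase, and the lymphocyte genes Gimap3 and Cd69, which had no read in any wild type library. H2-Q6, Car2 and Gimap3 were by far highest in Bud31-vKO library 2, at 330, 231 and 217 CPM. In Bud31-vKO libraries 1 and 3 H2-Q6 measured 26.3 and 7.32 CPM, Car2 11.8 and 20.3 CPM, and Gimap3 10.5 and 2.07 CPM. The lower genes were Isyna1, an enzyme of inositol synthesis, with a log2 fold change of -2.42, and the predicted gene Gm31579, which had no read in any Bud31-vKO library. H2-K1 and H2-Q6 belong to a family of similar genes, so the split of reads between its members is uncertain. Among well expressed genes called by DESeq2, Hmgcs1, an enzyme of cholesterol synthesis, was lower at 45.0 ± 10.3 against 218 ± 40.0 CPM, and Cdca7, a gene of the cell cycle, at 89.0 ± 17.4 against 299 ± 83.9 CPM (SD, n = 3 each). Zfp36l2, an RNA-binding protein, was higher at 226 ± 5.31 against 68.5 ± 21.5 CPM, Eif4a2, an RNA helicase of translation, at 715 ± 108 against 309 ± 59.6 CPM, and Tns1, a focal adhesion protein, at 159 ± 24.3 against 58.5 ± 4.00 CPM (SD, n = 3 each). Their adjusted p by edgeR was 0.9997 in each case.

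Germ cell genes and cell cycle genes were lower as groups in the Bud31-vKO libraries. Of 13 pan-germ-cell markers tested, 12 had a log2 fold change below 0, with a median of -0.65, and the summed level of the 14 markers in the table was 3629 ± 292 CPM in wild type and 2128 ± 309 CPM in Bud31-vKO (SD, n = 3 each) with no overlap. Of 26 genes of the G1/S transition and DNA replication, 22 were below 0, with a median of -0.73. The median was -0.67 over 27 meiosis genes, 22 of them below 0, -0.38 over 22 genes of G2 and mitosis, 17 of them below 0, and -0.42 over 17 genes of the piRNA pathway, 13 of them below 0. In the mean log2 CPM per library the genotypes overlapped for the meiosis, G2/M and piRNA lists, and not for the G1/S list. With camera at a preset correlation of 0.01, adjusted over the 24 lists tested, p was 0.000603 for G1/S, 0.00984 for the pan-germ-cell and for the meiosis list, 0.0291 for G2/M and 0.0436 for the piRNA list. None of these calls held with an estimated correlation, where the adjusted p was 0.761 for the G1/S, pan-germ-cell, meiosis and piRNA lists and 0.814 for G2/M.

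Few members of these lists stood out alone. In the pan-germ-cell list Mael passed when adjusted over the list alone (adjusted p = 0.0269). Dmrt1, a transcription factor of male germ cells, had a log2 fold change of -1.40 and Elavl2, an RNA-binding protein, one of -2.24. The germ cell helicase Ddx4 and the RNA-binding protein Dazl, added after their values were seen, had -0.82 and -0.52. In the piRNA list Mael passed when adjusted over the list alone (adjusted p = 0.0352), while Tdrd12 had -1.72, Henmt1 -1.92 and Tdrd6 1.97, and the last was -0.34 in the 4 libraries with the most genes detected. In the meiosis list, 0 genes passed when adjusted over the list alone. Its members Rec8, a cohesin of meiosis, Spo11, which makes the DNA breaks of recombination, and Meioc had log2 fold changes of -4.27, -3.14 and -2.94 at under 25 CPM in both groups. In the G1/S list Cdk2 passed when adjusted over the list alone (adjusted p = 0.00958), and Ccne1, the cyclin partner of CDK2, had -2.09 and E2f2 -2.57. In the G2/M list 0 passed, and Top2a had -1.13, Plk1 -2.38 and Kif20a -1.18. By edgeR no member of any list passed over all genes, while DESeq2 called Cdk2 and Mael.

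Single libraries decided several of these group calls. Of the 6 libraries, Bud31-vKO library 1 held the lowest sum of pan-germ-cell markers, 1805 CPM, and the highest sum of Sertoli cell markers, 1926 CPM. Without Bud31-vKO library 1 the adjusted p was 0.173 for G1/S, 0.173 for pan-germ-cell, 0.0880 for meiosis, 0.985 for G2/M and 0.484 for piRNA genes, and without wild type library 3 it was 0.209 for G1/S, 0.0613 for pan-germ-cell, 0.105 for G2/M and 0.209 for piRNA genes. The pan-germ-cell and piRNA lists also missed the threshold without Bud31-vKO library 3 (0.0524 and 0.0524), the G2/M list without Bud31-vKO library 3 (0.196) or wild type library 2 (0.177), and the piRNA list without wild type library 1 (0.0814) or 2 (0.0576). The piRNA list missed it also with a block for the library number (0.0539) and among genes with a mean of at least 50 CPM (0.138). The median log2 fold change of the G1/S genes was -0.42 without wild type library 3 and -0.45 without Bud31-vKO library 1, and that of the meiosis genes -0.40 without wild type library 3. For the G2/M genes it was -0.10 without Bud31-vKO library 1, where the camera direction turned to higher, -0.22 without wild type library 2, -0.77 without Bud31-vKO library 2 and -0.83 in the 4 libraries with the most genes detected. The piRNA median was -0.89 without Bud31-vKO library 3.

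Ribosomal and mitochondrial genes were higher as groups in the Bud31-vKO libraries. Mitochondrial genes held 5.46%, 4.73% and 3.03% of reads in wild type libraries 1 to 3 and 5.74%, 8.15% and 4.91% in Bud31-vKO libraries. These shares overlapped between the groups. Of 87 cytosolic ribosomal protein genes, 80 had a log2 fold change above 0, with a median of 0.54 (adjusted p = 2.9e-06 by camera with the preset correlation). All 11 mitochondrially encoded protein genes tested were above 0, with a median of 0.56, and 59 of 75 nuclear genes of oxidative phosphorylation, with a median of 0.39 (adjusted p = 0.00984 each). With an estimated correlation the adjusted p was 0.814 for the ribosomal list, 0.761 for the mitochondrially encoded list and 0.825 for the nuclear list. By edgeR no member passed over all genes or when adjusted over its list alone. The ribosomal members named by the rule had low counts, Rpl13a with a log2 fold change of 1.77, Rpl38 with 1.48 and Rpl23a with 1.39, all under 10 CPM in both groups. The mitochondrial members were mt-Nd6 with 1.09, which overlaps mt-Nd5 on the opposite strand, mt-Nd3 with 0.85 and mt-Co2 with 0.71. The nuclear members were Cox6b1 with 1.41, Atp5k with 1.32 and Uqcr11 with 1.31. Ribosomal protein genes have many processed copies in the genome, so their counts are uncertain where reads match several places. With camera at the preset correlation the ribosomal list passed in each of the 18 other settings, but with fry its adjusted p was 0.820. Its median was 0.29 without Bud31-vKO library 1 and 0.32 without wild type library 3. The mean log2 CPM of the ribosomal genes was 6.58, 6.38 and 5.56 in wild type libraries 1 to 3 and 7.13, 5.96 and 6.92 in Bud31-vKO libraries 1 to 3, lowest in the 2 libraries with the fewest genes detected. The nuclear list missed the threshold without Bud31-vKO library 1 (median 0.04, adjusted p = 0.272), without wild type library 3 (0.20, adjusted p = 0.101) and among genes with a mean of at least 50 CPM (adjusted p = 0.204), and its median was 0.69 without wild type library 1 and 0.66 without Bud31-vKO library 2. The mitochondrially encoded list missed it in the 4 libraries with the most genes detected (median 0.15, adjusted p = 0.515), without wild type library 3 (0.32, adjusted p = 0.101), without Bud31-vKO library 2 (0.37, adjusted p = 0.272) and without Bud31-vKO library 1 (adjusted p = 0.0569).

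**Figure D2:**
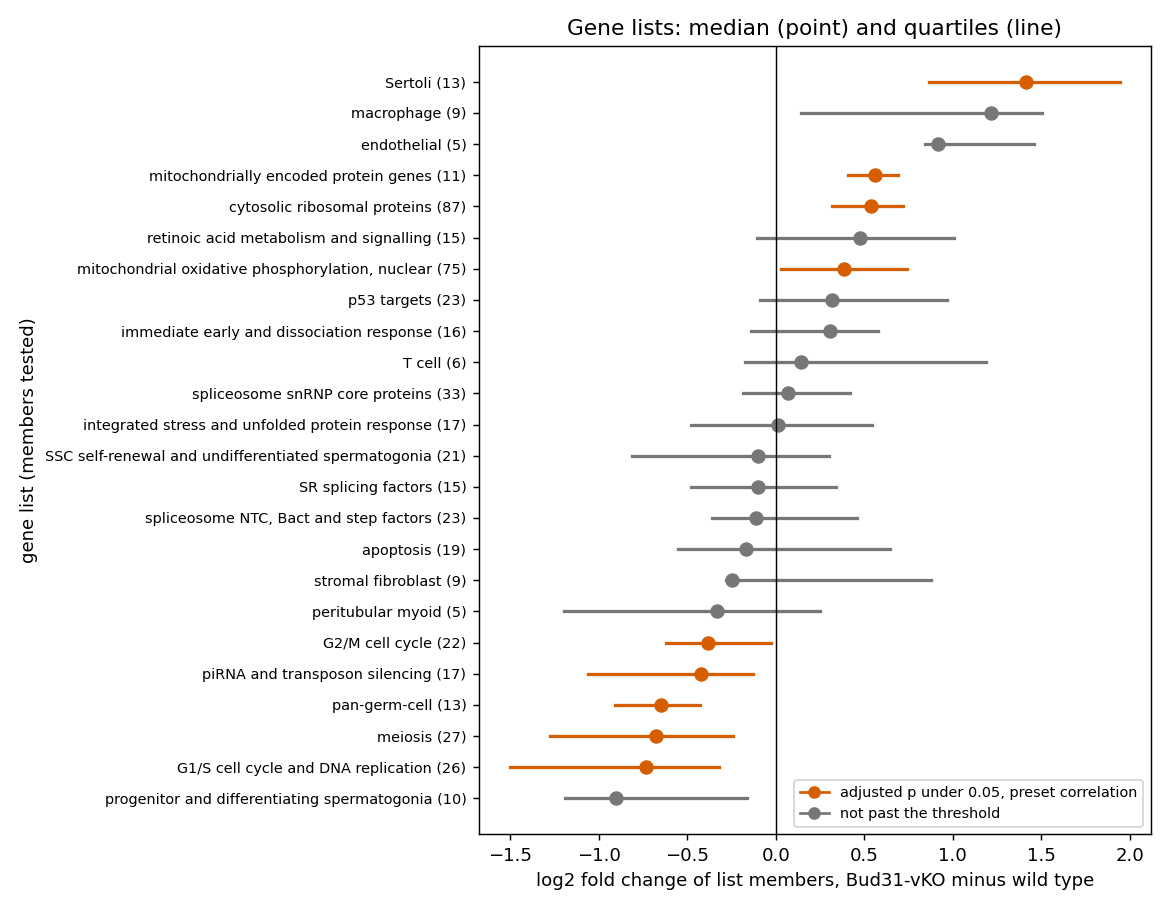
Log2 fold change (horizontal axis, Bud31-vKO minus wild type) of the members of 24 gene lists, with the median as a point, the quartiles as a line and the number of members tested beside each list name. The 9 lists in orange passed 5% by camera with a preset correlation, 5 of them lower and 4 higher, and 0 of them passed with an estimated correlation.

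Lists of stem cell identity and splicing genes gave no call, which does not exclude a shift. The 21 genes of stem cell self-renewal and undifferentiated spermatogonia had a median log2 fold change of -0.10 (adjusted p = 0.652, and 0.858 with an estimated correlation). Among them Etv5 had -1.60, Nanos3 -1.46 and Zbtb16 -1.45, the last -0.17 without wild type library 3, and Sall4 and Gfra1, added after their values were seen, -0.61 and -0.31. Thy1, a marker of the sort, had 0.30 at 13.3 ± 2.85 CPM in wild type and 16.4 ± 12.1 CPM in Bud31-vKO (SD, n = 3 each). Kit, the receptor against which the cells were sorted, was counted at 30.7 ± 31.4 and 12.8 ± 11.8 CPM (SD, n = 3 each), a log2 fold change of -1.26 that ranged from -2.07 without Bud31-vKO library 1 to -0.20 without wild type library 2. The 10 genes of progenitor and differentiating spermatogonia had a median of -0.90 (adjusted p = 0.401), with -5.13 for Dmrtb1 and 2.83 for Prdm9 at low counts, and 2.43 for the retinoic acid receptor Rarg. Of the spliceosome, 23 genes of the complexes that hold BUD31 or act around it had a median of -0.11 (adjusted p = 0.911), and 33 core proteins of the small nuclear ribonucleoproteins one of 0.07 (adjusted p = 0.652). Isy1, a partner in the catalytic spliceosome, had 1.66, the helicases Dhx16 and Dhx8 -1.36 and -1.06, and the core genes Ddx23, Snrnp40 and Prpf6 -1.09, -1.05 and 0.89. In the 15 SR protein and splicing kinase genes, with a median of -0.10 (adjusted p = 0.989), Srsf6 had -0.87 and Clk1 1.12 with unadjusted p of 0.0129 and 0.00938 by edgeR, both 0.0965 when adjusted over the list alone, and Tra2a had -0.64. The camera direction of this list turned under other scalings. With 1 library left out, the median ranged from -0.34 to 0.12 for the stem cell list (above 0 without wild type library 1), from -0.87 to -0.23 for the progenitor list, from -0.17 to 0.05 for the complexes around BUD31 (above 0 without wild type library 3), from 0.05 to 0.21 for the core proteins and from -0.22 to 0.04 for the SR protein list (above 0 without Bud31-vKO library 3). The progenitor median was -0.23 without wild type library 1, -0.26 without wild type library 2 and -0.25 without Bud31-vKO library 2.

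Stress and signalling lists did not pass either. The 23 p53 targets had a median log2 fold change of 0.32 (adjusted p = 0.0833, and 0.761 with an estimated correlation), with 2.94 for Bbc3, a killer protein of the BCL2 family, 2.64 for the polymerase Polk and 1.58 for the death receptor Fas. The 19 apoptosis genes had a median of -0.17 but a mean and a camera direction above 0 (adjusted p = 0.765), with Apaf1 at 1.46. For 17 genes of the integrated stress and unfolded protein response the median was 0.01, the mean slightly below 0 and the adjusted p 0.765. Hsp90b1, a chaperone of the endoplasmic reticulum, had -1.10 there with an unadjusted p of 0.00983 by edgeR (0.167 when adjusted over the list alone), Sesn2 -1.20 and Atf3 0.85. The 16 immediate early genes, which respond to tissue digestion, had a median of 0.31 (adjusted p = 0.170), with Hspa1a at 1.36 and Jund at 1.25, and passed without wild type library 2 (0.0491). The 15 genes of retinoic acid metabolism and signalling had a median of 0.47 (adjusted p = 0.106), with the receptor Rara at 1.56 and the degrading enzyme Cyp26b1 at 1.45. With 1 library left out, the median ranged from 0.11 without Bud31-vKO library 2 to 0.44 for p53 targets, from -0.51 without Bud31-vKO library 3 to 0.22 without wild type library 2 for apoptosis genes and from -0.13 without wild type library 3 to 0.44 without wild type library 2 for the stress response. It ranged from 0.01 without wild type library 1 to 0.79 without wild type library 2 for immediate early genes and from 0.06 without Bud31-vKO library 1 to 0.76 without wild type library 1 for retinoic acid genes. In the 4 libraries with the most genes detected the p53 median was -0.04.

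Markers of other testis cells were present in the sorted samples of both genotypes. All 9 stromal fibroblast markers reached 10 CPM in each of the 6 libraries, and their sum was 14468 ± 6411 CPM in wild type and 11962 ± 3032 CPM in Bud31-vKO (SD, n = 3 each), above that of the germ cell markers in every library. Col1a1 and Col3a1, the main collagens, measured 3931 ± 2082 and 4036 ± 2426 CPM in wild type and 3245 ± 1314 and 3095 ± 1087 CPM in Bud31-vKO, and Dcn 3269 ± 592 and 2692 ± 222 CPM (SD, n = 3 each). Their log2 fold changes were -0.28, -0.38 and -0.28, and those of the collagens turned to 0.26 and 0.25 without wild type library 3. The stromal list had a median of -0.25, a mean and camera direction above 0 and an adjusted p of 0.765, with Pdgfra at 0.93 and Lum at -0.91. Its median ranged from -0.40 without wild type library 2 to 0.26 without wild type library 3 and was 0.30 in the 4 libraries with the most genes detected. Sertoli cell markers were higher as a group, 12 of 13 above 0 with a median of 1.41 (adjusted p = 0.0291 by camera with the preset correlation). With an estimated correlation the adjusted p was 0.761. Bud31-vKO library 1 held a sum of 1926 CPM of these markers and the other 5 libraries between 147 and 507 CPM, and without it the median was 0.33 and the adjusted p 0.392, while the adjusted p was 0.383 without wild type library 2 and 0.101 without wild type library 3. The inhibin subunits Inhbb and Inha had 3.56 and 2.33 and Cldn11, a tight junction gene, -3.06.

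The remaining cell types gave no call. The 9 macrophage markers had a median of 1.22 (adjusted p = 0.0616), with Fcer1g at 1.88, Tyrobp at 1.71 and C1qa at -2.10, and passed without wild type library 1 (0.0476) or with the filter of at least 5 CPM (0.0423). The 5 endothelial markers had a median of 0.92 (adjusted p = 0.142), with Kdr at 1.81, Flt1 at 1.46 and Egfl7 at 0.92, and passed without wild type library 1 (0.0224), without Bud31-vKO library 2 (0.0122) or in the 4 libraries with the most genes detected (0.0421). For the 5 peritubular myoid markers the median was -0.33 (adjusted p = 0.765), with Acta2 at -1.19, Cnn1 at -1.24 and Myh11 at 0.48, and for 6 T cell markers it was 0.14 (adjusted p = 0.765), with Cd3e at 1.74, Cd3g at 1.47 and Cd2 at -1.17. The Leydig cell and erythroid lists had 3 members each past the usual filter, too few for a list test with all libraries. They passed in 0 of the 6 other settings in which each could be tested (smallest adjusted p = 0.221 and 0.515 by camera). Where 1 library left out allowed a test, the Leydig median ranged from -3.54 without Bud31-vKO library 3 to 1.03 without Bud31-vKO library 2, and the erythroid median from 0.38 to 1.41. Their members past the usual filter were Nr5a1 with 1.24, Cyp11a1 with 0.90 and Star with 0.34, and Hbb-bs with 0.998, Hba-a1 with 0.93 and Alas2 with 0.66. With 1 library left out, the median ranged from 0.47 to 2.24 for macrophage, from 0.46 to 2.81 for endothelial, from -0.79 to -0.04 for peritubular myoid and from -0.72 without Bud31-vKO library 3 to 1.12 without wild type library 3 for T cell markers. Haemoglobin genes have near-identical copies, so their counts are uncertain.

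**Figure D3:**
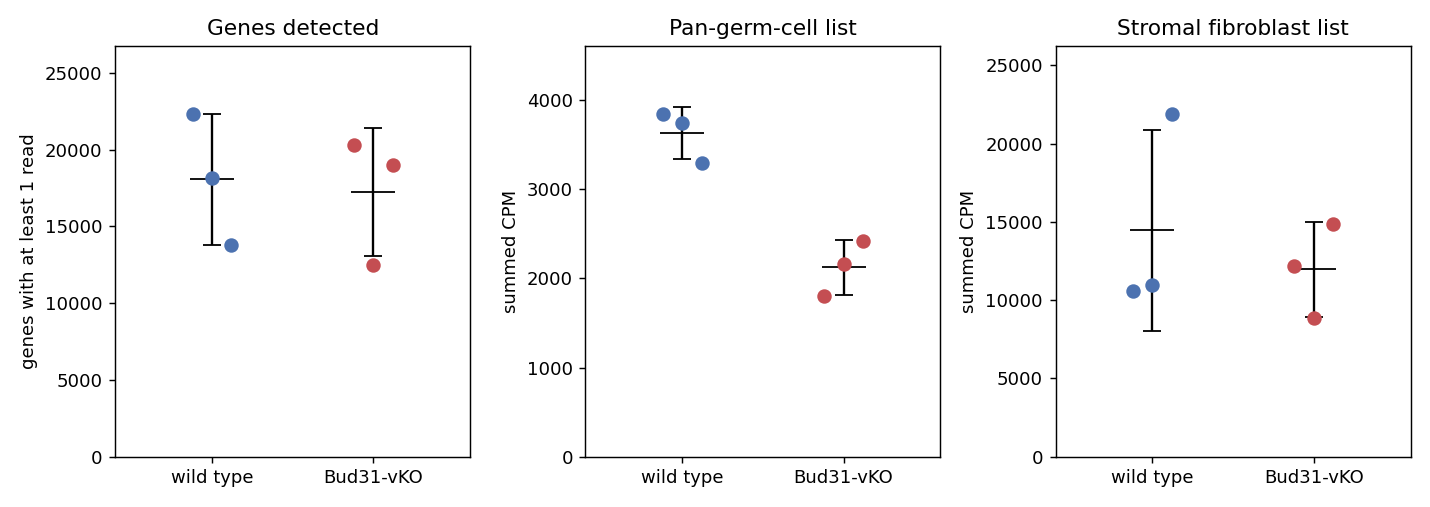
Genes with at least 1 read (left), summed CPM of the pan-germ-cell markers (middle) and of the stromal fibroblast markers (right) in each library, wild type in blue and Bud31-vKO in red, with mean and SD (n = 3 per group); all axes start at 0. Germ cell marker sums lie between 3296 and 3842 CPM in wild type and between 1805 and 2421 CPM in Bud31-vKO, while the other measures overlap.

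The number of exons of a gene bore almost no relation to its fold change. Across 13172 protein-coding genes, which are not independent replicates, Spearman's rho between the log2 fold change and the largest number of exons in a transcript of the gene was -0.03. The median log2 fold change was 0.15 for 247 genes with 1 exon, 0.09 for 2062 genes with 2 to 4 exons, 0.02 for 4329 genes with 5 to 9, -0.08 for 4356 genes with 10 to 19 and 0.04 for 2178 genes with 20 or more. In a rank regression with transcript length, GC content and mean expression the coefficient of the exon number was -0.05. The sign turned without wild type library 3 (0.0116) and without Bud31-vKO library 1 (0.0134). Counts per gene do not show splicing itself.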

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

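Robust dispersion, the mean of at least 50 CPM and the 4 libraries with the most genes detected were tests added after the results were seen. Bud31 kept its direction in each setting, with a log2 fold change of -1.19 to -0.80 when single libraries were left out. The count of 0 genes higher and 0 lower held except with no low-count filter, which gave 5 higher and 2 lower, and with DESeq2, which gave 17 higher and 30 lower. Of 9 lists shifted, 0 remained with an estimated correlation and 0 with fry, and leaving out 1 library gave 1 (without Bud31-vKO library 1) to 10 (without wild type library 1). The rank correlation of log2 fold change with exon number ranged from -0.0677 to 0.0134 with 1 library left out. A block for the library number gave 0 genes and 8 lists, and log2 fold changes of -5.03 for Cyp11a1, -1.08 for Hbb-bs and -0.91 for Hba-a1. The deviations of libraries with the same number correlated at 0.19, 0.04 and -0.08 for numbers 1 to 3. The highest correlation with another number was 0.11, 0.0045 and 0.11. These values do not settle whether the numbers mark pairs. Of 108 named genes, 18 turned direction somewhere, and for 70 the log2 fold change turned or moved by over 1.5 times when 1 library was left out. With limma-voom the log2 fold change was -1.17 for Cyp11a1, -1.99 for Hbb-bs and -2.91 for Hba-a1. In the 4 libraries with the most genes detected it was -0.34 for Tdrd6, 0.93 for Ddx23, -0.22 for Prpf6, 0.0704 for Tra2a, 0.52 for Col1a1 and 0.49 for Col3a1. With 1 library left out it ranged from -2.81 to 0.36 for Nanos3, -1.43 to 0.19 for Gfra1, -0.48 to 0.66 for Thy1, -3.74 to 0.40 for Ddx23, -0.14 to 1.37 for Prpf6, -2.64 to 2.002 for Hspa1a, -7.27 to 1.49 for Cyp11a1, -0.23 to 0.90 for Star, -1.11 to 2.52 for Myh11, -0.60 to 0.26 for Col1a1, -0.64 to 0.25 for Col3a1, -11.00 to 2.06 for C1qa, -0.51 to 2.76 for Cd3e, -10.06 to 2.97 for Hbb-bs, -7.14 to 2.62 for Hba-a1 and -0.74 to 1.91 for Alas2. Many of these genes have low counts in some libraries, and the cause was not tested. A gene left untested by a stricter filter has no value there. With the dispersion of these libraries, simulated 16-fold changes were recovered for 8 of 50 genes, so a count of 0 leaves large changes open.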

Other observations

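The tests on Cdk2 in the germ cell share and in 4 libraries, on G1/S and cholesterol genes against germ cell genes, on counts of genes over splits, and all tests on natural killer cell genes were chosen after the results were seen, and the cholesterol, histocompatibility and natural killer cell lists were themselves written after values of their genes had been seen. Genes of cholesterol synthesis were lower together in the Bud31-vKO libraries. Hmgcs1, which makes the precursor of mevalonate, measured 218 ± 40.0 CPM in wild type and 45.0 ± 10.3 CPM in Bud31-vKO, Sqle, which oxidizes squalene, measured 161 ± 58.1 and 51.1 ± 14.9 CPM, and Idi1, an isomerase of the pathway, 97.6 ± 11.9 and 16.6 ± 13.2 CPM (SD, n = 3 each). All 21 genes of the list had a log2 fold change below 0, with a median of -1.54.

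Genes of natural killer cells were higher in the Bud31-vKO libraries. Cd69, an activation marker of lymphocytes, had no reads in wild type and 33.3, 32.8 and 35.0 CPM in Bud31-vKO libraries 1 to 3. The receptor gene Klrb1c had no reads in wild type and 9.50, 16.5 and 8.06 CPM, and the granule protease Gzma measured 2.22 ± 3.002 CPM in wild type and 42.7 ± 30.7 CPM in Bud31-vKO (SD, n = 3 each). The 20 listed genes that had not prompted the list summed to 14.1, 171 and 36.7 CPM in wild type and 297, 1093 and 232 CPM in Bud31-vKO libraries 1 to 3. Among the 20, Eomes, a transcription factor of these cells that is also in the stem cell list and had too few reads to be tested, went the other way, with 4.17 ± 3.65 CPM in wild type and 0.17 ± 0.30 CPM in Bud31-vKO (SD, n = 3 each). The gene Gm31579 was also lower, with 37.8, 23.2 and 58.2 CPM in wild type and no reads in Bud31-vKO.

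For cholesterol synthesis, the 19 genes left without Hmgcs1 and Sqle were lower by camera (p = 8.2e-10 with the preset correlation, and adjusted p = 0.0404 over 3 such lists with an estimated correlation). Their median differed from that of the pan-germ-cell list by -0.78 (bootstrap standard error 0.27 over genes). This argues against a lower share of germ cells as the whole cause. It does not exclude it, as that standard error does not measure the spread between libraries. A trend on transcript length, GC content and expression does not account for the lower level, since the median was -1.43 before and -1.45 after its removal. Of the 10 splits of the libraries, too few for a share under 0.05, 1 gave a p as small, the real one, and the smallest other p was 0.000355. A change in the sterol pathway of the cells, or in which of the other cell types were sorted, may underlie it, and neither was tested.

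For natural killer cell genes, the 12 tested genes that had not prompted the list were higher by camera (p = 8.88e-10 with the preset correlation). With an estimated correlation the adjusted p was 0.0484 over 3 lists. That is not independent support, here or in the tests below. Klrk1, Klre1, Il2rb, Cd7 and Tbx21 among the 12 passed the filter mainly through their Bud31-vKO reads. Such cells or their RNA in the samples may underlie the rise, as a gate on THY1 also takes lymphocytes. Not all markers went along. Ptprc, a leukocyte gene of the macrophage list, measured 3.94, 54.7 and 68.1 CPM in wild type and 18.8, 328 and 12.9 CPM in Bud31-vKO. Among the Bud31-vKO libraries, Ncr1 and Prf1 had reads in library 3 alone. A strain variant on chromosome 6 is argued against for the 9 tested genes on other chromosomes. Their median log2 fold change was 2.35 (bootstrap standard error 0.47 over genes, not over libraries). Il2rb, Cd7 and Tbx21 are among these 9, so this median is not free of the filter. A chromosome 6 variant cannot be told apart for the 10 listed genes on that chromosome. Of these 10, 6 had no read in wild type and reads in Bud31-vKO, Cd69, Klrb1c, Klrc1 and Gimap3 among them. Gm31579 lies on chromosome 6 too, starting at 50909770, and Gimap3 starts at 48764464. Klrb1c, Cd69 and Klrc1 lie in a separate stretch, from 128778485 to 129678973. Without Bud31-vKO library 2 the camera p was 2.14e-05 with the preset correlation. Splits of all 6 libraries that mix the genotypes gave p as small as 6.32e-08, so this p does not exclude that library as the cause. The sums of the 20 genes in Bud31-vKO libraries 1 and 3, 297 and 232 CPM, still lay above the highest wild type sum of 171 CPM. The stromal markers argue against a lower share of germ cells as the whole cause. Their median log2 fold change lay 3.21 below that of the list (standard error 0.71 over genes). The mean log2 CPM of the list relative to that of the stromal markers was 3.72 higher in Bud31-vKO (standard error 1.42 over libraries). Against all other markers, however, that difference of means was 3.26 with a standard error of 1.83, and the groups overlapped. Of 10 splits, too few for a share under 0.05, 1 had a p as small, the real one, with 6.32e-08 as the smallest other.

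For Cdk2, the ratio to the mean of the pan-germ-cell markers differed by -1.37 on the log2 scale (standard error 0.34, no overlap), which argues against a lower share of germ cells as the whole cause. The tables also argue against dropout, as the log2 fold change was -1.97 in the 4 libraries with the most genes detected, with 504 reads or more in each library. Reads of Pmel reached 11.5% of Cdk2 in a wild type library, above the bound of 10% set beforehand. By that bound, reads of Pmel are not excluded as a cause. Pmel held at most 19.7 CPM where the groups differed by 173 CPM. It was itself low in Bud31-vKO libraries 1 and 3. In Bud31-vKO library 2 Pmel measured 16.3 CPM, within the wild type values, while Cdk2 measured 41.1 CPM. In that 1 library the low Cdk2 level thus did not go with a low Pmel count. As the use of strand is not known, reads of the shared exons may be missing from the Pmel count, so it cannot settle the question. An effect of Bud31 loss on Cdk2 remains a hypothesis, and a different mix of other cell types may also contribute.

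After removal of the same trend the median was 0.43 for the ribosomal list (0.54 before) and -0.65 for the G1/S list (-0.73 before). The G1/S median lay at -0.085 relative to that of the pan-germ-cell list, with a bootstrap standard error of 0.23 over genes. A lower share of germ cells thus cannot be told apart for the G1/S list. The histocompatibility list without H2-K1 was not shifted by camera (adjusted p = 0.394 over the 3 lists).

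Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. At unadjusted p under 0.05 the real split had 443 genes and the highest other 1183, and 3 of the 10 splits had as many as the real one. That highest split set wild type library 1 with Bud31-vKO libraries 1 and 3 against the rest, that is the 3 libraries with the most genes detected against the others, which is a structure of the samples apart from genotype. At adjusted p all 10 splits had 0 genes. For lists shifted, the real split had 9 and the highest other 7, so 1 of 10 was as large. For exon number the real absolute rank correlation was 0.0307 and the highest other 0.118, and 7 of 10 were as large.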
